A study of Mus musculus with 12 samples.

How the data were processed

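Total RNA from the pancreas of 12 mice was hybridised to 12 whole-transcript mouse arrays, 3 for each of the groups Kras normal, Kras IKK2 normal, PanIN and PDAC, per the labels. Per the labels the mice were male and 6 to 8 months old. The values analysed are log2 expression values for 35556 probe sets, made by the authors with robust multi-array average (RMA), per the submitters' processing notes. RMA in its usual form corrects background, applies quantile normalization and summarises the probes of a probe set, and its settings are not given in the sources used here. The version of RMA and the genome build are not given in the sources used here. Array data have no read depth, and the number of arrays limits the precision of each value.

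Probe sets were paired with genes by the array annotation, which listed 23410 of them. The 21789 probe sets with exactly 1 gene symbol were kept, 1621 with several symbols were left out, and 12146 with no listed gene entered no comparison of genes. Of several probe sets for a gene (999 genes) the one with the highest mean over the 12 arrays was used, which left 19938 genes. No filter on dim genes was applied. Values were not transformed or normalized again.

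Differences between groups were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes without trend or robust fitting), with a mean per group over all 12 arrays. Contrasts were Kras IKK2 normal minus Kras normal, PanIN minus Kras normal, PDAC minus Kras normal and PDAC minus PanIN. A gene counted as changed at a Benjamini-Hochberg adjusted p under 0.05 in its contrast. An F-test over the 9 arrays of Kras normal pancreas, PanIN and PDAC asked for any difference among these stages. The overlap of PanIN and PDAC changes was set against 50 simulations of unchanged groups that share simulated controls. Replicate numbers were not used as pairs, since 5 of 12 arrays were most alike to arrays of their own number, and correlations of same-number arrays after removing group means ran from -0.31 to 0.27.

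A total of 26 gene lists were tested with limma camera at a preset correlation of 0.01, and again with an estimated correlation. They covered acinar enzymes and transcription factors, ductal, gastric-type and PanIN, islet, fibroblast, macrophage, neutrophil, T cell, B and plasma cell, mast cell, endothelial, adipocyte and red blood cell genes. The others were NF-kB targets, the IKK and NF-kB pathway, Notch, MAPK output and EGFR ligands, proliferation, epithelial-mesenchymal transition, unfolded protein response, injury, interferon, glycolysis and hypoxia, p53 and senescence, and immediate early genes. Members without a probe set of their own were left out, among them Amy2a5, Ins1, Nfkb1, Stat1 and Cdkn1a, and the red blood cell list kept 2 members and the p53 list 6. Direction counts were also adjusted over the list alone.

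The genes named for each contrast were the 10 largest rises and the 10 largest falls among genes with adjusted p under 0.05 and no overlap between the arrays of both groups, leaving out predicted and clone-named genes. Up to 4 members with the smallest p from each list, Ikbkb and Kras were added. Groups, contrasts, tests, lists, this rule and the alternatives were fixed before the data were examined, except where the text says otherwise. The sex-linked genes Xist, Kdm5d, Eif2s3y and Uty were compared with the sex given in the labels. A group mean no higher than the mean 95th percentile of olfactory receptor genes in its arrays was taken as background, a level chosen after the data were seen (4.26 in Kras normal, 4.64 in Kras IKK2 normal, 3.68 in PanIN and 3.48 in PDAC arrays).

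The alternatives were a block for replicate number, the arrays of the contrast alone, leaving out the dimmest 25% or 50% of genes, quantile normalization, centring on the median or the 75th percentile, the mean of probe sets, each probe set alone, eBayes with trend and robust fitting, array weights, a fold change of at least 2, an estimated correlation and leaving out each array in turn. Keeping only genes above the 95th percentile of olfactory receptor genes was added after the data were seen. The procedure was tested on simulated data with 200 of 19938 genes changed. It recovered 81.1% to 92.1% of changes of 1 on the log2 scale and 99.0% to 100% of changes of 2, and 2.66% to 7.84% of its calls were false. The simulated noise was independent between genes, at 1 SD per gene for all groups. The real median SD was 0.247 in Kras normal pancreas and 0.129 in PDAC, and many more genes were called. These shares therefore need not hold for the real calls. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6.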

Results

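RNA from the pancreas of 12 mice was measured on Affymetrix whole-transcript arrays (Mouse Gene 1.0 ST), with 1 array per mouse and 3 mice in each of 4 groups. All mice carried Pdx1-cre, a transgene that produces Cre recombinase in the developing pancreas, and Kras LSL-G12D, an oncogenic Kras allele that Cre switches on by removing a stop cassette. The Kras normal group was pancreas of normal appearance from such mice. The Kras IKK2 normal group was pancreas of normal appearance from mice that also carried a conditional allele of IKK2, the kinase encoded by Ikbkb that frees NF-kB from its inhibitors. The PanIN group was pancreatic intraepithelial neoplasia, the precursor lesion of pancreatic cancer, and the PDAC group was pancreatic ductal adenocarcinoma, both from mice with Pdx1-cre and the Kras allele alone. The values were log2 expression values from robust multi-array average (RMA), as the authors deposited them, for 19938 genes. The median of each array lay between 3.86 and 4.19, and the number of arrays limits the precision of every value. The first principal component held 67.2% of the variance and set both normal groups apart from both lesion groups, and the second, with 12.6%, set the normal groups apart from each other. Correlations across the 19938 genes between arrays of a group ran from 0.947 to 0.967 in Kras normal pancreas and from 0.981 to 0.993 in the other groups, over genes that are not independent replicates.

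**Figure D1:**
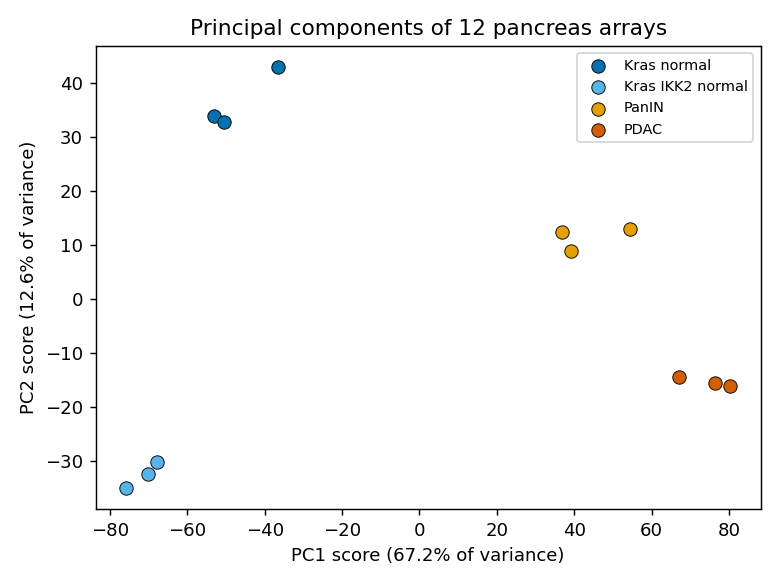
Principal component scores of the 12 arrays on the first component (67.2% of variance, x axis) and the second (12.6%, y axis), with 1 point per array, coloured by group. The 3 arrays of each group lie together and apart from the other groups.

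Ikbkb had a log2 level of 4.96 ± 0.26 (SD, n = 3) in Kras normal and 4.97 ± 0.20 in Kras IKK2 normal pancreas, a difference of 0.00 (SE 0.15, limma adjusted p = 0.99). Ikbkb rose in the lesions, to 6.02 ± 0.05 in PanIN and 6.57 ± 0.11 in PDAC. The increases over Kras normal pancreas were 1.06 and 1.60 (SE 0.15 each, limma adjusted p = 1.3e-05 and 2.5e-08). PDAC exceeded PanIN by 0.54 (limma adjusted p = 0.016), a call that ended after quantile normalization, where the difference was 0.34. The call also ended without PanIN replicate 2 or 3 or PDAC replicate 2 or 3, at adjusted p from 0.051 to 0.082. Which part of Ikbkb the probe set covers is not given in the sources used here, and the RNA came from whole tissue, so the equal levels in both normal groups check nothing about the conditional allele. Kras was not analysed here, because no probe set was paired with it. Xist, the RNA that silences an X chromosome in females, divided the groups although the labels give all 12 mice as male. Its level was 6.51 ± 0.38 in Kras normal pancreas and 6.97 ± 0.16 in PDAC, but 4.13 ± 0.32 in Kras IKK2 normal pancreas and 3.98 ± 0.26 in PanIN. The mean of the Y-linked genes Kdm5d, Eif2s3y and Uty ran the other way, at 2.63 in Kras normal pancreas, 2.59 in PDAC, 3.33 in Kras IKK2 normal pancreas and 3.91 in PanIN. Sex-linked transcripts therefore differed along with each comparison except PDAC against Kras normal pancreas, where Xist differed by 0.46, a call that quantile normalization ended with the sign turned (-0.09).

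**Figure D2:**
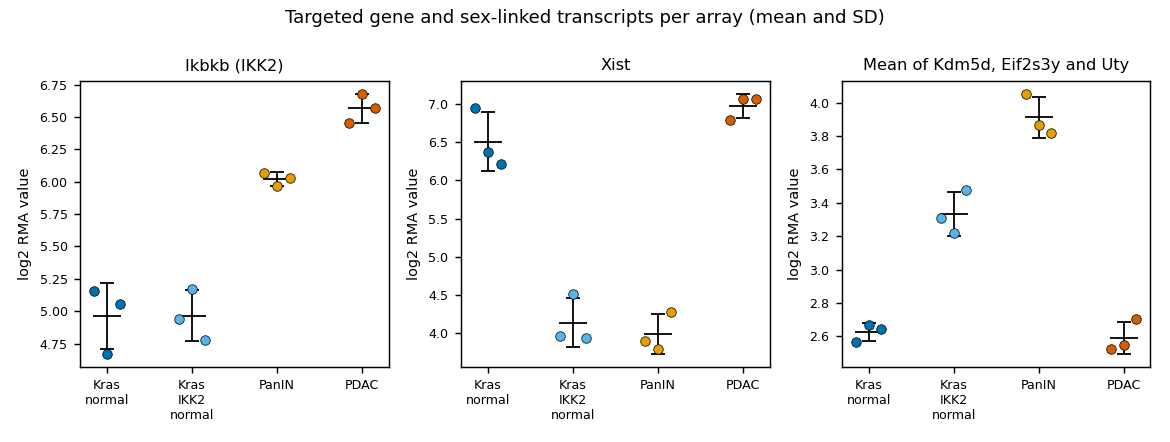
Log2 RMA values of Ikbkb, Xist and the mean of Kdm5d, Eif2s3y and Uty per array (points), with the mean and SD of the 3 arrays of each group (bars). Xist lies above 6 in every Kras normal and PDAC array and below 5 in every Kras IKK2 normal and PanIN array.

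The comparison of both normal groups asks what the conditional IKK2 allele goes along with in pancreas of normal appearance. Gal, which encodes the neuropeptide galanin, fell from 8.01 ± 0.24 (SD, n = 3) in Kras normal pancreas to 3.18 ± 0.08, which lies at background, so the 28.5-fold difference is a lower bound (limma adjusted p = 9.8e-15). Small nucleolar RNAs, which guide the chemical modification of ribosomal RNA, were among the strongest rises. Snord104 rose 25.8-fold, from 7.30 ± 0.15 to 11.98 ± 0.09, and Snora3, Snord35b and Snora7a rose by 3.35, 3.21 and 3.13 on the log2 scale. Errfi1, an inhibitor of EGF receptor signalling, rose 8.97-fold. Among the other large falls were Ndufa4, a subunit of the respiratory chain (fell by 2.74), Micos10, which shapes the inner mitochondrial membrane (fell by 3.12), and Gas5, the host transcript of several small nucleolar RNAs (fell by 2.69, with 3 of its 4 probe sets going that way). Trdn, a muscle calcium release protein, rose by 3.68 in the probe set used, but only 11 of its 19 probe sets rose in value.

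Of 18 measured islet genes, 10 fell and 1 rose in the Kras IKK2 normal group. Iapp, the beta cell peptide amylin, fell by 2.78, Pyy, the gut and islet hormone peptide YY, fell by 2.31, and Gcg, the precursor of glucagon, fell by 1.56. Insulin was not among them: Ins2, chosen after its values were seen, had a mean of 7.32 against 7.24 (limma adjusted p = 0.68). The islet list had a median change of -0.62, and its test passed (limma camera, adjusted p = 5.9e-03) but not with another correlation (adjusted p = 0.365 with an estimated correlation). Immediate early genes, which respond within minutes to stimulation and to tissue handling, went up in 7 of 12 cases and down in 1, with a median of 0.47. Egr1 rose by 2.18, Jun by 1.54 and Dusp1 by 1.12, and the list passed its test (adjusted p = 5.9e-03) with adjusted p = 0.371 with an estimated correlation. The other 24 lists did not pass. Of 31 NF-kB target genes, 2 rose, among them Ccl2, a chemokine that attracts monocytes (0.98), and 8 fell, among them Tnfaip2 (fell by 0.98) and Lcn2 (fell by 0.90), for a median of -0.19. Of 16 genes of the IKK and NF-kB pathway, 3 rose and 4 fell. Rela, a subunit of NF-kB, rose by 0.91, and Tnfrsf1a, a receptor for TNF, fell by 0.85.

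Most digestive enzyme genes of acinar cells did not pass the test: 3 of 21 rose and 3 fell, with a median of 0.04 and a mean of -0.14. The largest fall was that of Prss3, a trypsinogen (fell by 2.73), whose near-identical copies a probe set may not tell apart. Of 6 acinar transcription factors, Ptf1a fell by 0.63, a call that ended without 1 array of the Kras IKK2 normal group, and none rose. The median of these factors was nevertheless positive, at 0.21, and 0.64 after quantile normalization. Ductal genes rose in 3 of 15 cases and fell in 5, with Epcam and Krt19 down by 1.17 and 0.92 (log2 changes of -1.17 and -0.92). The gastric-type and PanIN list had 3 rises and 5 falls among 20 (median 0.10), and the fibroblast and matrix list 1 and 9 among 24, including Col3a1 (fell by 1.35). Rises and falls were 3 and 2 of 18 macrophage genes, 3 and 0 of 12 neutrophil genes, 1 and 0 of 12 T cell genes and 1 and 3 of 12 B and plasma cell genes. They were 1 and 0 of 8 mast cell genes, 3 and 2 of 11 endothelial genes, 1 and 2 of 10 adipocyte genes and 0 and 2 of 2 red blood cell genes. For signalling they were 1 and 2 of 16 Notch genes, including Lfng (1.29), 2 and 3 of 19 MAPK output and EGFR ligand genes, and 1 and 3 of 13 regulators of the epithelial-mesenchymal transition. Proliferation genes fell in 8 of 21 cases and rose in 1, unfolded protein response genes fell in 6 of 18 and rose in 4, and injury response genes fell in 6 of 12 and rose in 1, with Reg3g down 3.30-fold. Interferon genes rose in 4 of 18 cases and fell in 2, glycolysis and hypoxia genes rose in 4 of 17 and fell in 6, and p53 and senescence genes fell in 3 of 6. Adjusted over the list alone, the counts of rises and falls were 2 and 3 acinar enzymes, 4 and 5 ductal, 4 and 5 gastric-type, 1 and 11 islet, 3 and 3 endothelial, 3 and 6 IKK and NF-kB pathway, 4 and 7 unfolded protein response and 5 and 6 glycolysis genes, and equal to those above for the other lists.

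Limma called 6972 of 19938 genes between the normal groups, 2206 up and 4766 down, of which 374 rose and 907 fell at least 2-fold. With the arrays of the contrast alone, 5256 were called. Of 1015 olfactory receptor genes, taken as background here, 207 rose and 100 fell, with a median of 0.03. The calls therefore include genes at background. Calls were nearly as frequent among olfactory receptor genes as among all genes, so list counts near that frequency are not particular to a list. The 3 arrays of each group did not overlap for 42.5% of genes, where chance gives 10%. Of the 111 named genes called, 48 had their lower group no higher than the 95th percentile of olfactory receptor genes there, among them Gal, Snora3, Snord35b, Gas5, Epcam, Tnfaip2, Ccl2 and Lcn2. Their changes are lower bounds only where the higher group lies above background, and the count did not check this. The median change of all genes was -0.12 and became -0.00 when arrays were centred on their 75th percentile, which turned the medians of the ductal, fibroblast, B and plasma cell, pathway, Notch, epithelial-mesenchymal and glycolysis lists positive. Quantile normalization turned those of the ductal, pathway, Notch, epithelial-mesenchymal, glycolysis and unfolded protein response lists, and median and test direction differed in sign for the macrophage, neutrophil, B and plasma cell, pathway, Notch, epithelial-mesenchymal and glycolysis lists.

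The comparison of PanIN with Kras normal pancreas asks what the precursor lesion adds. Genes of gastric-type mucous epithelium, which PanIN cells are known to express, rose in 18 of 20 cases and fell in 2, with a median of 3.16. Tff1, a secreted mucosal peptide, rose 46.2-fold from 5.32 ± 0.16 (SD, n = 3) to 10.85 ± 0.08 (limma adjusted p = 2.6e-16). Gkn1 and Gkn3, stomach surface proteins, rose by 5.44 and 5.58, and Ctse, a gastric protease, by 4.61. Genes of small-intestinal absorptive cells were also among the largest rises: Apoa1, an apolipoprotein, went from 5.11 ± 0.39 to 10.91 ± 0.28, Fabp1, a fatty acid binding protein, from 3.21 ± 0.15 to 8.40 ± 0.22, and Prap1 rose 68.9-fold. Ductal genes rose in 14 of 15 cases, with a median of 2.16. Krt19 rose from 5.86 ± 0.02 to 10.16 ± 0.05 and Tspan8 by 4.98. These gastric-type and ductal rises came along with those of the small-intestinal genes, and whole-tissue RNA does not tell which cells carried them.

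Fibroblast and matrix genes rose in 22 of 24 cases with no fall and a median of 2.36, including Col1a1, a chain of type I collagen (3.42), and Fn1, fibronectin (4.00). All 18 macrophage genes rose, with a median of 2.57, including Lyz2, lysozyme (3.70), and the complement gene C1qb (3.34). Endothelial genes rose in 9 of 11 cases (median 0.66). T cell genes rose in 6 of 12 cases and B and plasma cell genes in 6 of 12, with 1 fall. Cd3g, a T cell receptor chain, rose by 3.46 and Jchain, the joining chain of secreted antibodies, by 4.89. Small-intestinal genes, a list chosen after the values were seen, rose in the same contrast in 35 of 42 cases, and the intestine also holds T and plasma cells. The list tests for these lymphocyte groups were lost with another correlation (adjusted p = 0.115 and 0.076 with an estimated correlation). Adipocyte genes rose in 7 of 10 cases and fell in 1 (adjusted p = 0.05002 with an estimated correlation, not under the threshold), with Car3 up by 1.36 and Pparg by 1.23. Neutrophil genes did not pass as a list (4 rises and 1 fall of 12). The largest rise among them was Ltf, lactoferrin (3.87), which glandular epithelium also secretes. Neither of the 2 called mast cell genes of 8 rose, and their list median was 0.01 and their mean -0.11, with the median at -0.21 under 75th percentile centring. Both measured red blood cell genes fell, Alas2 by 1.66 and Slc4a1 by 1.27 (adjusted p = 0.0853 with an estimated correlation).

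NF-kB target genes rose in 19 of 31 cases and fell in 1, with a median of 0.77. Lcn2, a siderophore-binding protein, rose from 4.59 ± 0.29 to 9.58 ± 0.15, and Vcam1, an adhesion molecule for leukocytes, by 3.13. Genes of the IKK and NF-kB pathway rose in 10 of 16 cases and fell in 2, with Myd88, an adaptor of Toll-like receptors, up by 1.82. MAPK output and EGFR ligand genes rose in 11 of 19 cases, led by the ERK phosphatase gene Dusp6 (2.66). Interferon response genes rose in 13 of 18 cases and fell in 2, with Psmb8, an immunoproteasome subunit, up by 2.67 and Irf7 by 2.31. Glycolysis and hypoxia genes rose in 14 of 17 cases and fell in 1 (adjusted p = 0.0627 with an estimated correlation), injury response genes rose in 8 of 12 and fell in 2 (adjusted p = 0.132 with an estimated correlation), and regulators of the epithelial-mesenchymal transition rose in 7 of 13 (adjusted p = 0.115 with an estimated correlation). Examples were Pfkp, a phosphofructokinase (2.55), Cd44 (2.83) and Tgfb1 (2.14). The p53 and senescence list (3 rises of 6, adjusted p = 0.115 with an estimated correlation) and the immediate early list (6 rises and 1 fall of 12, adjusted p = 0.132 with an estimated correlation) also lost their calls. Notch genes (5 rises and 2 falls of 16), proliferation genes (8 and 2 of 21) and unfolded protein response genes (3 and 10 of 18) did not pass. Notch2 rose by 1.68, Pcna, the sliding clamp of DNA polymerase, by 0.78, and Dnajc3, an endoplasmic reticulum chaperone, fell by 1.14. The Notch median of 0.21 became -0.01 under 75th percentile centring.

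Acinar genes were lower in PanIN, where 15 of 21 digestive enzyme genes fell and none rose, with a median of -0.51 (adjusted p = 0.132 with an estimated correlation). Ctrc, a chymotrypsin, fell from 12.25 ± 0.06 to 10.14 ± 0.09, and Prss3 by 3.76. In Kras normal pancreas the median level of these enzymes was 12.78, close to the highest values of the arrays, where differences can be understated. Of 6 acinar transcription factors 4 fell, Rbpjl by 2.43 and Nr5a2 by 1.42 (adjusted p = 0.157 with an estimated correlation). Mat1a and Gnmt, enzymes of methionine metabolism, fell by 3.99 and 2.88, and Gal fell by 5.21. Islet genes went both ways, with 5 rises and 6 falls of 18, a median of -0.34, a mean of 0.12 and no call for the list. Ppy, pancreatic polypeptide, rose by 3.00 and Pyy by 2.49, while Pcsk1, a prohormone convertase, fell by 1.35.

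Limma called 10176 genes between PanIN and Kras normal pancreas, 4895 up and 5281 down, of which 1778 rose and 321 fell at least 2-fold. Arrays of both groups did not overlap for 51.6% of genes, where chance gives 10%. The lower group lay at background, by the same rule, for 31 of the 119 named genes called, among them Prap1, Gkn3, Fabp1, Tspan8, Gal, Ltf, Cd3g, Vcam1 and Pfkp. Such changes are lower bounds only where the higher group lies above background. The median change of all genes was -0.12, 0.03 after median centring and -0.34 after 75th percentile centring, which gave 5856 up and 2767 down or 3498 up and 9304 down. Of 1015 olfactory receptor genes, which the pancreas is not known to use, 464 fell and 1 rose, with a median of -0.39, so many falls were of dim genes. Falls were more frequent among them than among all genes, so falls of dim list members are not particular to their list. Adjusted over the list alone, the counts of rises and falls were 0 and 18 acinar enzymes, 15 and 0 ductal, 5 and 8 islet, 23 and 0 fibroblast, 9 and 1 adipocyte, 20 and 1 NF-kB target, 8 and 1 proliferation and 4 and 0 p53 genes, and equal to those above for the other lists.

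PDAC against Kras normal pancreas asks the same of the carcinoma. All 21 digestive enzyme genes fell, with a median of -3.17: Ctrc from 12.25 ± 0.06 (SD, n = 3) to 6.76 ± 0.11 (limma adjusted p = 6.1e-17), Cela1, an elastase, by 4.56 and Prss3 by 6.54. All 6 acinar transcription factors fell, Rbpjl by 4.21 and Bhlha15 by 3.80, although their list lost its call with another correlation (adjusted p = 0.0981 with an estimated correlation). All 18 islet genes fell, with a median of -1.38, including Iapp from 9.60 ± 0.29 to 3.71 ± 0.03, Gcg by 5.29 and Ins2, insulin, by 2.82. All 24 fibroblast and matrix genes rose (median 3.28), including Col1a1 from 6.63 ± 0.12 to 11.53 ± 0.02 and Tnc, tenascin C, by 4.17. All 15 ductal genes rose (median 2.56), with Krt19 up 30.9-fold and Krt7 by 4.83. Gastric-type and PanIN genes rose in 15 of 20 cases and fell in 3, led by Ctse, which went from 4.49 ± 0.10 to 10.14 ± 0.09.

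All 17 glycolysis and hypoxia genes rose in PDAC, with a median of 2.43. Slc2a1, the glucose transporter GLUT1, rose from 5.31 ± 0.17 to 9.50 ± 0.05, and Car9, a carbonic anhydrase of hypoxic cells, by 3.91. MAPK output and EGFR ligand genes rose in 18 of 19 cases (median 1.37), among them Dusp4 (3.74), Dusp6 (3.67) and the cyclin gene Ccnd1 (3.03). Proliferation genes rose in 15 of 21 cases (median 0.81), including Mcm6, a helicase subunit of DNA replication (1.88). Regulators of the epithelial-mesenchymal transition rose in 10 of 13 cases and fell in 1, with the intermediate filament gene Vim up by 3.68 and Tgfb1 by 3.35. NF-kB target genes rose in 20 of 31 cases and fell in 1, with Lcn2 at 10.00 ± 0.04, and pathway genes rose in 11 of 16 and fell in 2, with Tnfrsf1a up by 1.78. Immediate early genes rose in 11 of 12 cases and fell in 1, with Dusp1 up by 2.75, and p53 and senescence genes rose in 5 of 6, with Cdkn2b, an inhibitor of cyclin-dependent kinases, up by 1.73. All 18 macrophage genes rose (median 2.67), 7 of 12 neutrophil genes rose and 1 fell, and 9 of 11 endothelial genes rose. Ctss, a lysosomal protease, rose by 4.54, Mmp9, a matrix metalloproteinase, by 1.55, and Eng, endoglin, by 2.15.

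Notch genes rose in 7 of 16 cases and fell in 2 (adjusted p = 0.0847 with an estimated correlation), with Notch2 up by 2.62 and Jag1 by 1.49. Unfolded protein response genes fell in 10 of 18 cases and rose in 3 (adjusted p = 0.545 with an estimated correlation), with Edem1 down 3.67-fold. The lists of T cell (2 rises and 2 falls of 12), B and plasma cell (2 and 2 of 12), mast cell (2 and 0 of 8), adipocyte (1 and 5 of 10), red blood cell (0 and 2 of 2), injury response (7 and 3 of 12) and interferon genes (9 and 3 of 18) did not pass. Within them Cd3g rose by 2.06, Jchain by 2.70, Cpa3, a mast cell carboxypeptidase, by 1.66 and Cxcl9, a chemokine, by 2.06, while Car3 fell by 2.34 and the acinar secretory genes Reg1 and Reg3d fell by 2.27 and 3.67. The T cell list had a median of -0.20 and a mean of 0.00, and the B and plasma cell list a median of -0.02 and a mean of 0.16. Both medians were positive after median centring and after quantile normalization (T cell 0.06 and 0.01, B and plasma cell 0.25 and 0.25), and the mast cell median of 0.04 became -0.29 under 75th percentile centring.

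Limma called 13435 genes between PDAC and Kras normal pancreas, 6142 up and 7293 down, of which 2814 rose and 969 fell at least 2-fold. Arrays did not overlap for 66.5% of genes, where chance gives 10%. In 24 of the 113 named genes called the lower group lay at background, among them Tnc, Dusp4, Car9, Cd3g, Cpa3 and Cxcl9. Such changes are lower bounds only where the higher group lies above background. The median change of all genes was -0.15, 0.11 after median centring and -0.47 after 75th percentile centring, which gave 7808 up and 3541 down or 4283 up and 10873 down. Of 1015 olfactory receptor genes, 640 fell while 1 rose, so falls were more frequent among them than among all genes. Adjusted over the list alone, 16 proliferation and 6 p53 genes rose, T cell genes had 1 rise and 2 falls and B and plasma cell genes 1 of each, and the other lists gave the counts above.

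Taking Kras normal pancreas, PanIN and PDAC together, limma's F-test called 12474 genes among 9 arrays. Their group means rose through the 3 stages in 4590 genes, such as Col1a1 and Krt19, and fell through them in 4923, such as Ctrc and Rbpjl. Means were highest in PanIN in 1510 genes, such as Tff1, and lowest there in 1451. PanIN and PDAC shared 4313 genes above and 4729 below Kras normal pancreas, 9042 in all, and 134 genes went opposite ways. Independent lists of the same sizes would share 1508 and 1932. Log2 changes of both lesions correlated at r = 0.835 across genes, which are not independent replicates. In 50 simulations of unchanged groups that shared 3 simulated control arrays, 0 genes were called alike and r was 0.5004. With no gene changed, few or no shared calls were bound to result, so that count is no support. The noise was drawn independently at 1 SD per gene for all groups. The real median SD was 0.247 in Kras normal pancreas and 0.129 in PDAC, so the simulations may understate what shared controls add. The covariance was 0.588 against 0.0142 in the simulations, a difference of 0.574, and the shared sign held for 88.8% of genes against 66.7%. The 3 control arrays are too few to split, so part of the excess may come from sharing them.

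**Figure D3:**
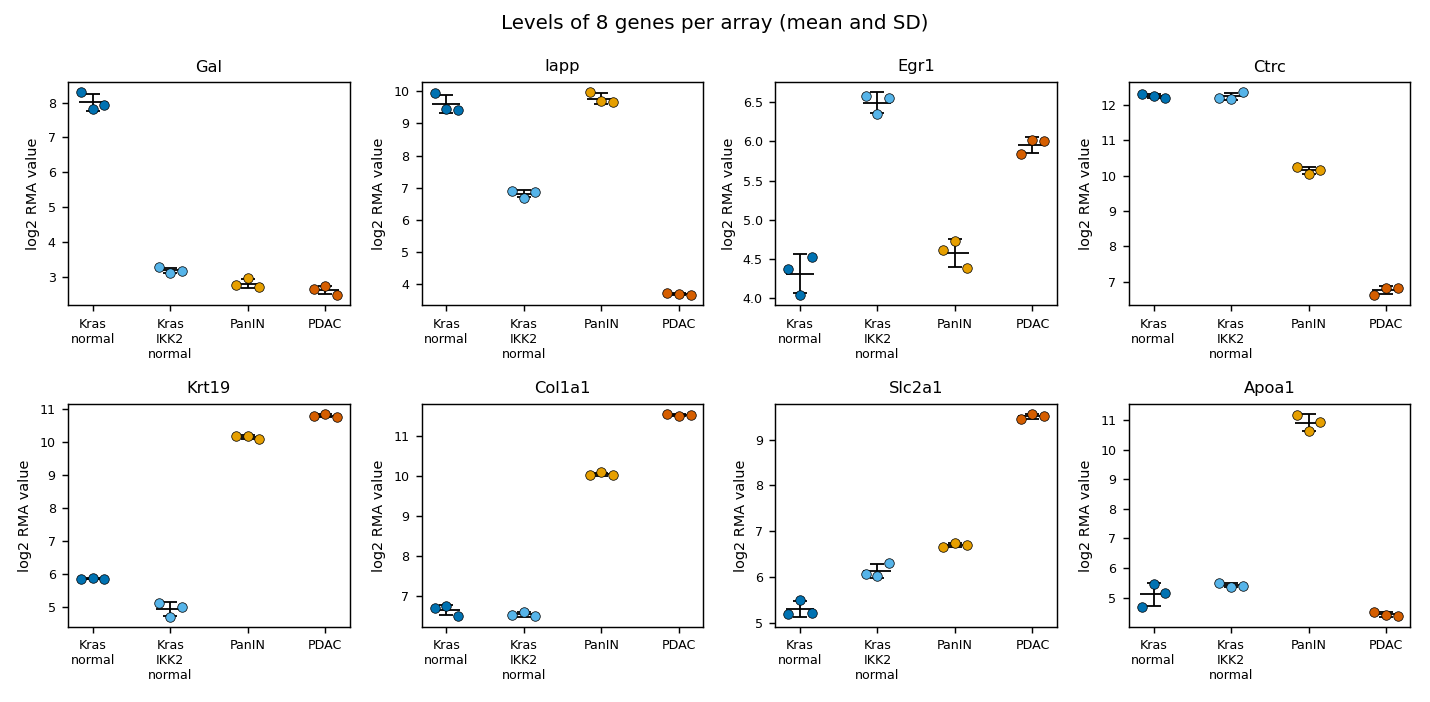
Log2 RMA values of 8 named genes per array (points), with the mean and SD of the 3 arrays of each group (bars). Gal is high in Kras normal pancreas alone among the 4 groups, Ctrc and Iapp are lowest in PDAC, and Apoa1 is highest in PanIN.

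PDAC against PanIN asks what separates the carcinoma from its precursor lesion. Small-intestinal absorptive genes made up most of the largest falls: Apoa1 fell from 10.91 ± 0.28 (SD, n = 3) to 4.44 ± 0.08 (limma adjusted p = 3.7e-16), and Fabp1, Fabp2, Apoa4, Alpi and Mttp fell by 5.96, 5.77, 5.93, 5.42 and 5.26. Gastric-type and PanIN genes fell in 13 of 20 cases and rose in 4, with Muc13, a membrane mucin, down by 6.06 on the log2 scale (-6.06) and Gkn1 down 11.9-fold. These falls came along with those of the small-intestinal genes, and whole-tissue RNA does not tell which cells carried them. Islet genes fell in 13 of 18 cases with no rise (median -1.41), Iapp from 9.76 ± 0.17 to 3.71 ± 0.03 and Ppy by 4.63. All 21 digestive enzyme genes fell (median -2.62), Cela1 by 3.89, as did 5 of 6 acinar transcription factors (adjusted p = 0.0567 with an estimated correlation), Bhlha15 by 2.58. In the other direction, glycolysis and hypoxia genes rose in 14 of 17 cases (median 1.54): Slc2a1 from 6.70 ± 0.04 to 9.50 ± 0.05, Ndrg1 by 2.43, Hk2, hexokinase 2, by 2.37 and Vegfa by 2.26.

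MAPK output and EGFR ligand genes rose in 18 of 19 cases (median 1.10), led by Hbegf, an EGFR ligand (2.59), and Dusp4 (1.86). Fibroblast and matrix genes rose in 19 of 24 cases (median 1.15), with Tnc up by 1.82 and Col1a1 by 1.48, and proliferation genes in 10 of 21 (median 0.54), with Rrm2, a ribonucleotide reductase subunit, up by 1.64. Immediate early genes rose in 9 of 12 cases (median 0.79), Dusp1 by 1.68. Msln, mesothelin, rose 6.35-fold, and the granule protease genes Mcpt8, known from basophils, and Mcpt1 rose 12.9-fold and 5.86-fold. Lymphocyte genes fell: 7 of 12 T cell genes (median -0.79), such as Cd8a by 1.52, and 5 of 12 B and plasma cell genes (median -0.35), such as Jchain by 2.19. They fell along with the small-intestinal genes, of which 37 of 42 fell and 1 rose (median -2.29). Interferon response genes fell in 9 of 18 cases (median -0.54), Psmb8 by 1.34, and adipocyte genes fell in 7 of 10 and rose in 1 (median -1.10), Car3 by 3.70.

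Ductal genes rose in 8 of 15 cases and fell in 1, with Krt7 up by 2.01 and Krt20 down 3.55-fold (adjusted p = 0.0595 with an estimated correlation). Macrophage genes rose in 5 of 18 cases (adjusted p = 0.235 with an estimated correlation) and neutrophil genes in 4 of 12 (adjusted p = 0.0567 with an estimated correlation), with S100a8 up by 0.95. Pathway genes of IKK and NF-kB rose in 3 of 16 cases (adjusted p = 0.0521 with an estimated correlation) and Notch genes in 5 of 16 (adjusted p = 0.0521 with an estimated correlation), with Jag1 up by 1.09. Regulators of the epithelial-mesenchymal transition rose in 8 of 13 cases (adjusted p = 0.0567 with an estimated correlation), with Tgfb1 up by 1.21, and p53 and senescence genes in 2 of 6 (adjusted p = 0.0735 with an estimated correlation). Injury response genes fell in 6 of 12 cases and rose in 3 (adjusted p = 0.231 with an estimated correlation), with Reg3d down 4.49-fold. Unfolded protein response genes fell in 8 of 18 cases and rose in 2 (adjusted p = 0.565 with an estimated correlation), and their median of -0.03 became 0.08 after median centring. NF-kB target genes did not pass as a list: 4 of 31 rose and 2 fell, with Ptgs2, cyclooxygenase 2, up by 1.62 and Ccl20 down 4.25-fold. The mast cell (3 rises of 8), endothelial (2 of 11) and red blood cell lists (1 of 2) did not pass either, and the endothelial median of 0.04 became -0.03 after quantile normalization and -0.06 after 75th percentile centring.

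Limma called 3703 genes between PDAC and PanIN, 2371 up and 1332 down, of which 466 rose and 438 fell at least 2-fold. Arrays did not overlap for 40.0% of genes, where chance gives 10%, and the count was 2234 after quantile normalization and 6521 with array weights. Of the 114 named genes called, 13 had their lower group at background, among them Fabp1, Fabp2, Alpi and Muc13. Such changes are lower bounds only where the higher group lies above background. The median change of all genes was -0.01, 0.11 after median centring, with 3358 up and 923 down, and -0.11 after 75th percentile centring, with 1709 up and 1915 down. Adjusted over the list alone, the counts of rises and falls were 0 and 6 acinar transcription factors, 4 and 14 gastric-type, 0 and 15 islet, 20 and 0 fibroblast, 7 and 0 macrophage, 0 and 9 T cell, 5 and 2 NF-kB target, 4 and 0 pathway, 7 and 1 Notch, 12 and 0 proliferation, 9 and 0 epithelial-mesenchymal, 3 and 8 unfolded protein response, 4 and 6 injury response, 1 and 10 interferon, 15 and 0 glycolysis, 3 and 0 p53 and 10 and 0 immediate early genes, and equal to those above for the other lists.

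**Figure D4:**
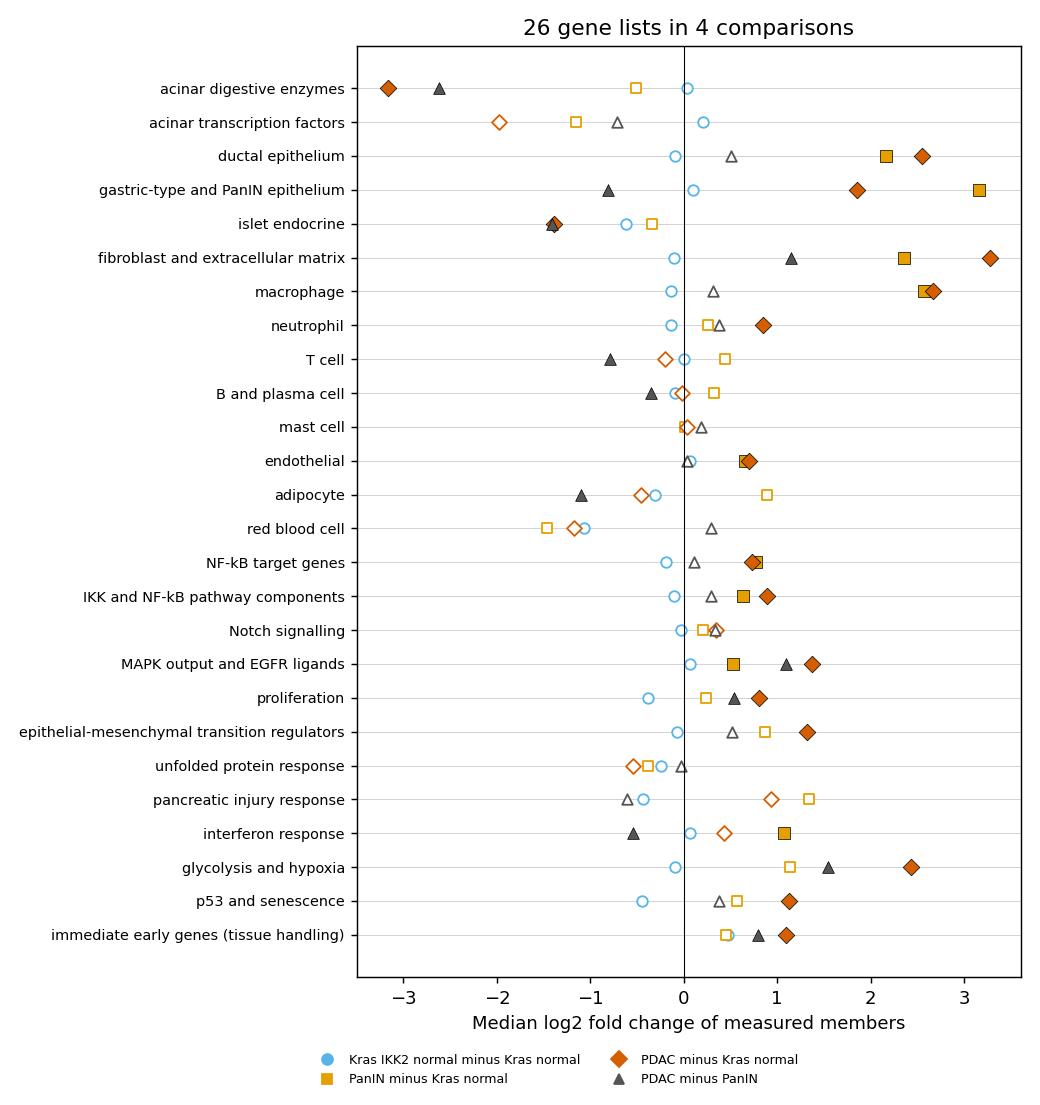
Median log2 fold change of the measured members of 26 gene lists (x axis) in 4 comparisons of 3 arrays against 3, with filled symbols where the list passed limma camera with an estimated correlation and open symbols where it did not. Medians near 0 change sign with the scaling of the arrays, such as those of the Notch, mast cell and B and plasma cell lists.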

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

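The comparisons below were chosen after the values were seen. Probe sets with no listed gene, which no comparison of the report uses, also differed from the control group. Of 12146 such probe sets, 1162 were called and at least 2-fold higher in Kras IKK2 normal than in Kras normal pancreas, and 1315 at least 2-fold lower (median of all -0.18). In PanIN 466 were higher and 660 lower (median -0.32), and in PDAC 701 were higher and 1205 lower (median -0.37). What these probe sets measure is not given in the sources used here, and no explanation was tested.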

How the results depend on the processing

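Keeping only genes above the 95th percentile of olfactory receptor genes was chosen after the data were seen. A fold change of at least 2, a stricter threshold by construction, left 1281 genes between the normal groups, 2099 for PanIN, 3783 for PDAC and 904 for PDAC against PanIN, and 1694 shared by both lesions. Leaving out the dimmest 50% of genes, so that fewer were tested, gave 5938 for PanIN, 7289 for PDAC, 7250 in the F-test and 5367 shared. PDAC against PanIN had 2234 genes after quantile normalization and 6521 with array weights, and the cause was not tested. Quantile normalization also lowered the Ikbkb difference between PDAC and PanIN to 0.34 and turned Xist in PDAC against Kras normal pancreas from 0.46 to -0.089, and the cause was not tested. With an estimated correlation 0 lists passed between the normal groups, 9 for PanIN and 12 for PDAC against PanIN, and the cause was not tested. Leaving out 1 array gave 5406 to 7145 genes between the normal groups, 7474 to 11224 for PanIN, 11570 to 13890 for PDAC, 2475 to 3550 for PDAC against PanIN, 10563 to 13418 in the F-test and 6710 to 10120 shared. Lists passing then were 2, 19 to 21, 17 to 20 and 21 to 22, and Ikbkb differences -0.14 to 0.10, 0.91 to 1.16, 1.46 to 1.70 and 0.49 to 0.60, in the same order of contrasts. The split into rises and falls moved with scaling: 3555 up and 4191 down between the normal groups after quantile normalization, and 3215 and 3366 after 75th percentile centring. Without the dimmest 50% the split was 4334 up and 1604 down for PanIN and 5337 and 1952 for PDAC, and above the olfactory receptor level 4909 and 2705, and 6139 and 3429. The replicate block gave 6961, 10112, 13437 and 3680 genes. The arrays of the contrast alone gave 5256, 7798, 12130 and 5098 genes, in the same order. The main fit used 1 spread per gene over all 12 arrays. The median SD was 0.247 in Kras normal pancreas and 0.129 in PDAC, so this shared spread does not suit every contrast equally. Of the named results, each a gene in a contrast, calls were lost for 27 under quantile normalization, 18 under 75th percentile centring, 13 with the arrays of the contrast alone, 7 with array weights and 5 with median centring, and gained for 11, 9, 3, 8 and 8. Over all fits without 1 array, 92 such calls were lost and 11 gained. The arrays give no depth, and dim genes near background limit what small differences can show.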

Other observations

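The gene families here, the small intestine, enterocyte, goblet and Paneth, gastric and snoRNA host lists, and all tests except those over splits of the arrays were chosen after the values were seen. Immunoglobulin segments rose in PanIN against Kras normal pancreas in 8 of 12 cases and fell in 1, with a median of 2.32 (limma camera, adjusted p = 0.0389 with an estimated correlation). Igha, the IgA heavy chain of mucosal antibodies, rose by 3.28 and Ighm, the IgM heavy chain, by 3.06, and both fell in PDAC against PanIN, by 2.65 and 2.59, along with the small-intestinal genes described below. Chemokine genes of the CC and CXC types, which guide leukocytes, rose in PanIN in 21 of 32 cases and fell in 1 (median 0.80), with Ccl6 up by 2.96 and Ccl17 by at least 2.73. Ccl25, known from the small intestine, rose by at least 3.15 and fell by at least 3.63 from PanIN to PDAC, since its lower levels lay at background. Cathepsin genes, which encode lysosomal proteases, rose in PanIN in 11 of 17 cases and fell in 1 (median 1.10), with Ctsh up by 3.51. The MHC class II genes H2-Aa and H2-Ab1, which present antigen to T cells, rose in PanIN by 3.52 and 3.86, but of 29 MHC genes 11 rose and 5 fell (adjusted p = 0.0994 with an estimated correlation), with a median of -0.03 that became 0.23 after quantile normalization and 0.12 after median centring. All 18 macrophage genes rose in the same contrast (median 2.57), and macrophages carry cathepsins, chemokines and MHC class II. Mast cell protease genes rose in PDAC against PanIN in 3 of 4 cases (median 1.69).

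In Kras IKK2 normal against Kras normal pancreas, families of protein synthesis, secretion and respiration had negative medians, which quantile normalization made smaller. Aminoacyl-tRNA synthetases, which charge tRNA with amino acids, fell in 13 of 16 cases (median -0.93, and -0.58 after quantile normalization), with Eprs and Nars down by 1.41 each (log2 changes of -1.41). Translocon and signal peptide genes, which move proteins into the endoplasmic reticulum, fell in 15 of 21 cases and rose in 1 (median -0.92 and -0.54). Respiratory chain and ATP synthase genes fell in 60 of 85 cases and rose in 9 (median -0.74 and -0.45), among them Ndufb7 by 2.12 and Atp5k by 2.19. Ribosomal protein genes fell in 33 of 57 cases and rose in 5 (median -0.58 and -0.31). None of these 4 families passed with an estimated correlation (adjusted p = 0.407 to 0.422). Part of the medians came from Kras normal replicate 1, whose family means lay above those of replicates 2 and 3. For the synthetases they were 7.42, 6.97 and 6.94, against 6.38, 6.10 and 6.35 in the Kras IKK2 normal arrays. In each family every Kras normal array lay above every Kras IKK2 normal array. The median SD between arrays of a group was 0.247 in Kras normal pancreas, 0.138 in Kras IKK2 normal pancreas, 0.150 in PanIN and 0.129 in PDAC.

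Xist was high and Y-linked genes low in the Kras normal and PDAC arrays, although the labels give all mice as male. Array scaling is argued against, since the smallest Xist difference between Kras normal pancreas and PanIN over 3 scalings was 2.38. Single arrays exchanged between groups are argued against too, as 0 arrays lay on the other side of the Xist midpoint of 5.43 from the rest of their group. Female animals in the Kras normal and PDAC groups are a candidate explanation: all 6 of these arrays had a Y-linked mean no higher than the 75th percentile of olfactory receptor genes, below every other array by at least 0.52, but the 3 Kras IKK2 normal arrays also lay under that percentile of their own, so Y-linked genes set only PanIN apart from background and Xist carries the rest. No explanation other than these 3 was tested, and if these animals were female, sex differed along with 3 of the 4 contrasts.

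Small-intestinal genes were high in PanIN, where 35 of 42 rose and 4 fell against Kras normal pancreas (median 3.10). Stomach tissue that holds parietal and chief cells is argued against as the source, since 0 of 9 of their genes rose. Stomach tissue without these cells is not addressed by that list, and gastric-type genes rose in 18 of 20 cases and fell in 2. Small-intestine tissue in the PanIN samples and intestinal differentiation of the lesion cells cannot be told apart here. For the tissue, 18 of 20 enterocyte genes and 6 of 7 goblet and Paneth cell genes were higher in PanIN than in PDAC, but these lists were chosen for the pattern, so the counts decide nothing. For differentiation, Cdx2, the intestinal master regulator, rose by 0.58 (SE 0.19, limma adjusted p = 0.016), but intestinal tissue would bring Cdx2 as well. Atoh1, the regulator of secretory cells, fell by 0.53 (limma adjusted p = 0.011) and Cdx1 differed by -0.32 (limma adjusted p = 0.083). Olfactory receptor genes had a median of -0.39 in this contrast, with 464 falls and 1 rise of 1015. Falls of the size seen for Atoh1 and Cdx1 therefore decide nothing about either explanation.

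Small nucleolar RNAs rose in Kras IKK2 normal pancreas in 35 of 53 cases and fell in 8, while 60 of 85 respiratory chain genes fell and 9 rose (adjusted p = 0.407 with an estimated correlation). The median level of the small nucleolar RNAs was 3.68 in Kras normal and 4.47 in Kras IKK2 normal pancreas. Both lie under the background levels of 4.26 and 4.64, so the typical member was at background in both groups. Of 1015 olfactory receptor genes, 207 rose and 100 fell in this contrast, with a median of 0.03. Array scaling is argued against, since the median of the small nucleolar RNAs exceeded that of all genes by 0.83 after quantile normalization and 0.81 before. Higher levels of the host transcripts are argued against, for the 16 measured of 28 listed. Their median was -0.82 (-0.55 after quantile normalization), with 1 rise and 10 falls. Transcript levels do not show how much the host genes were transcribed, so that question stays open. RNA recovery or quality differing between groups stays open: 12 small nucleolar RNAs were higher in PDAC than in PanIN, which share a genotype, with a median of 0.26 against 0.69 between the normal groups. The conditional allele stays open as well and was not tested apart from the group.

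For the contrasts of 3 arrays against 3, the 10 splits of 6 arrays are too few for a share under 0.05. The real split gave 6972 genes between the normal groups, 10176 for PanIN, 13435 for PDAC and 3703 for PDAC against PanIN, each the highest of its splits (1 of 10), and the highest other split gave 0. For the F-test 1 of 100 splits of the 9 arrays, the real one, gave 12474 genes, and the highest other gave 8019. Chance is argued against but not excluded, since only 100 splits were counted. The count does not tell stage from other differences between the groups, such as that of the sex-linked transcripts.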
